A study of Homo sapiens with 7 samples.

How the data were processed

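Total RNA of 7 samples of an engineered human dermal matrix was amplified, biotin-labelled and hybridised to GLYCOv4 arrays, per the labels' protocols, 1 sample per array. The deposited values are log2 probe set summaries made by the authors with RMA, per the submitters' processing notes, a method that corrects background, quantile-normalizes arrays and summarises the probes of a set. The RMA version, its settings and the probe set annotation are not given in the sources used here. The array medians were not identical, so the scaling across arrays was itself varied below. The design text speaks of 3 replicates per condition, and 4 standard hormone arrays are labelled, all of which were used. No columns of other samples were present.

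The table held 1259 probe sets and 0 control probe sets, and it carries no detection calls, so signal over background is not known per probe set and no filter on dim ones was set in the main test. A group mean under the lowest quartile of all values (4.71) is named as such. Names came from the RefSeq accession in a probe set's ID, matched without version to a gene table of assembly GRCh38.p14, from which the results reported here take names only: 1043 probe sets matched 1 symbol each, 0 matched several, and 216 were unnamed. Of the 927 genes 93 had more than 1 probe set. By Affymetrix's suffixes in the IDs, 793 sets are unique to a transcript and 113 to a gene, while 266 may also detect related transcripts (s) and 87 may cross-hybridise (x). Of the genes named in the text, the main probe set is an s set for BMP4, BMP6, FGF13, ACVRL1, SLC35F2, GCNT1, COLEC12, FGFR1, HAS3, VCAN, MCOLN1, NCAM1, COG8 and IL1R2, and an x set for MST1, POMGNT1 and NEU1. The called sets of BMP1 and HGF at 0.62 and -0.54 are s sets too.

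Groups were taken from the sample titles. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior, two-sided) on the deposited log2 values of all 7 arrays, with no covariate, and Benjamini-Hochberg adjustment over 1259 probe sets. A call is an adjusted p under 0.05, and all changes are high minus standard hormone. SEs and 95% intervals are those of limma's moderated fit. A gene is represented by its probe set with the highest mean over all arrays. The test, the lists, the naming rule and most alternatives were fixed before the data were examined.

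The naming rule took 3 kinds of genes. The first were the 8 genes with the largest rise and the 8 with the largest fall among calls whose groups do not overlap, and only 5 representing probe sets fell. The second were HAS1, HAS2, HAS3, HYAL1, HYAL2, HYAL3, CD44, UGDH, TNFAIP6 and VCAN where measured, and TNFAIP6 was not among the named probe sets. The third were, from each list, up to 2 members with the largest rise and up to 2 with the largest fall among calls, or else the member with the smallest p as values only. Genes named after their values were seen are said to be so. The result of 1 gene that the rule takes is not reported here.

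Of 34 lists of pathways and cell type markers, the 28 with at least 5 measured genes were tested with camera (preset correlation 0.01), 1 probe set per gene, with Benjamini-Hochberg adjustment over the 28. Camera with an estimated correlation passed 0 lists and fry 5, while camera with the preset one passed 2. The lists were those of hyaluronan synthesis, hyaluronan breakdown and binding, sugar and sulfate donors, nucleotide sugar transporters, chondroitin and dermatan sulfate, heparan sulfate, proteoglycan cores, lysosomal breakdown, N-glycan assembly, N-glycan trimming, O-GalNAc glycans, sialyltransferases, fucosyltransferases, glycosphingolipids, galectins, lectin receptors, inflammatory cytokines, cytokine receptors, growth factors, growth factor receptors, TGF-beta and BMP, Notch and Wnt signalling, matrix proteins, glucocorticoid-induced and thyroid hormone-responsive genes, mucins, ER folding and 6 sets of cell type markers.

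The fit was tested on simulated data with each probe set's spread, scaled by group, and 200 of 1259 probe sets changed in each of 20 draws. It recovered 42.2%, 86.1%, 94.2% and 97.7% of changes of 0.5, 1, 1.5 and 2 on the log2 scale, with 3.17% of calls false. A list shifted by 0.5 was found by camera in 20 of 20 draws. Simulated errors were independent between probe sets. In the data the estimated correlation was 0.32 within the hyaluronan synthesis list and 0.58 within the leukocyte markers. Arrays of a group were simulated with the same spread, while limma's weights for the standard arrays, lower for a noisier array, ran from 0.152 to 1.35. The simulation thus does not show how the tests fare with correlated genes or with arrays of unequal spread.

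Alternatives were array medians subtracted, quantile normalization, leaving out the dimmest 25% or 50% of probe sets, a trended robust prior, array weights, the replicate number as a block, leaving out each array, a minimum of 1.5-fold, the mean over a gene's probe sets, an unmoderated statistic, and other list tests. Chosen after seeing the data were a separate spread per group, scaling to ribosomal protein probe sets, and leaving out standard arrays 2 and 3 together. Figures were drawn with matplotlib 3.10.9.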

Results

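RNA from an engineered human dermal matrix, a tissue built in culture to model the dermis, was measured on 7 glycogene arrays. GLYCOv4 is a custom array that carries genes of glycan synthesis and breakdown, lectins, proteoglycans, growth factors and cytokines. In the high hormone group, 3 arrays held RNA of cultures given 200 µg/ml hydrocortisone, a glucocorticoid, and 0.2 nM triiodothyronine (T3), the active thyroid hormone. In the standard hormone group, 4 arrays held RNA of cultures given 0.4 µg/ml hydrocortisone and 20 pM T3. The high dose was thus 500 times the standard one for hydrocortisone and 10 times for T3, and as both hormones differ between the groups their effects cannot be told apart. Per the title of the series, the question was how the 2 hormones regulate hyaluronan synthesis. The table held 1259 probe sets, of which 1043 were named as 927 genes. Array medians lay between 6.10 and 6.40 on the log2 scale. No label says whether the replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

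Under high hormone, the chemokine CXCL13, which attracts B cells, rose 54.1-fold (95% interval 32.8 to 89.1), from a log2 value of 4.39 ± 0.54 (SD, n = 4) to 10.15 ± 0.35 (SD, n = 3). Its standard level lay in the lowest quartile of all values (under 4.71), where a fold depends on the background. HS3ST2, a 3-O-sulfotransferase of heparan sulfate, rose 11.4-fold (SE 0.15 on the log2 scale), from 6.38 ± 0.25 to 9.89 ± 0.13. PRG4, the lubricating proteoglycan lubricin, fell by 3.32 on the log2 scale (SE 0.22, adjusted p = 0.000361), from 6.70 ± 0.41 to 3.38 ± 0.14, a level in the lowest quartile. The cell-surface proteoglycan GPC4 rose 4.76-fold, the intracellular fibroblast growth factor homologue FGF13 4.45-fold and thrombomodulin (THBD), an anticoagulant receptor, 4.32-fold, the last from a standard level in the lowest quartile. Midkine (MDK), a heparin-binding growth factor, rose 3.96-fold, the activin subunit gene INHBB 3.86-fold and CHST1, a keratan sulfate sulfotransferase, 3.83-fold. Besides PRG4, the genes whose main probe set fell were EEF1A1, a translation elongation factor (-1.26), the lymphatic growth factor VEGFC (-1.15), and GALNT5 (-0.82) and GCNT1 (-0.80), enzymes of mucin-type O-glycans. Of the 3 probe sets outside the named genes with the largest changes, uc001grt.1_psr1_s_at (-3.37, to a level in the lowest quartile) and uc004akf.1_psr1_at (-1.54) fell and uc002tmn.1_psr1_a_at rose (1.84), picked after their values were seen.

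**Figure D1:**
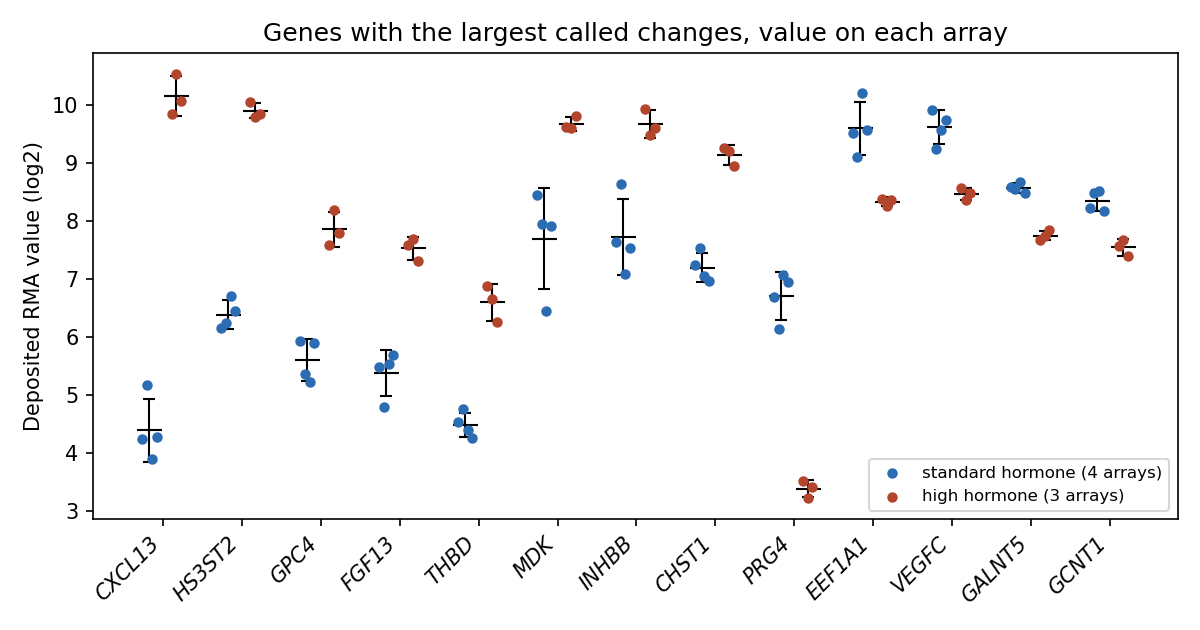
Deposited log2 value (vertical axis) of the genes with the largest called rises and falls, on each of the 4 standard hormone arrays (blue) and 3 high hormone arrays (red). Black bars are the group mean and SD. The groups do not overlap for any gene shown, and CXCL13 spans the widest gap, from a mean of 4.39 to one of 10.15.

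In all, 65 of 1259 probe sets passed an adjusted p of 0.05 in limma, 54 higher and 11 lower under high hormone, and they name 56 genes, 50 higher and 6 lower, HGF among the latter by dimmer probe sets only. At an unadjusted p under 0.05 the count was 234. The groups did not overlap at any of the 65, nor at 231 probe sets in all, which is 18.3% against 5.71% by chance. The split between higher and lower moved with the scaling: it was 42 against 24 with each array's median subtracted and 42 against 22 after quantile normalization. Subtracting array medians moved the median change of all probe sets from 0.03 to -0.10, and subtracting the median of ribosomal protein probe sets moved it to -0.08. The count was 18, 22 and 26 without high array 1, 2 and 3, and 59, 109, 91 and 40 without standard array 1, 2, 3 and 4. In every one of these 7 fits, 17 called probe sets passed, among them those of CXCL13, HS3ST2, GPC4, FGF13, THBD, CHST1, PRG4, GALNT5, LIFR and BMP6. Of the called genes named in the text, 16 kept the call of their main probe set in all 7 and the others lost it without at least 1 array, MDK, INHBB, EEF1A1, VEGFC and GCNT1 included. After quantile normalization MDK (1.83, adjusted p = 0.0544), SLC35E3 (0.75, 0.0544) and COLEC12 (1.07, 0.0649) also missed the threshold.

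No gene of hyaluronan synthesis or breakdown passed the test over all probe sets. HAS2, the main hyaluronan synthase of fibroblasts, lay at 8.02 ± 0.19 under high hormone and 9.10 ± 0.74 under standard hormone, a difference of -1.09 (SE 0.37, 95% interval -1.96 to -0.21, adjusted p = 0.163), with all 3 high arrays below all 4 standard ones. It passed with estimated array weights (-0.69, adjusted p = 0.0381) and without standard arrays 2 and 3 (-0.56, adjusted p = 0.0342), the latter a setting chosen after seeing the data. The other synthases differed by -0.10 (HAS1) and -0.08 (HAS3, adjusted p = 0.865), and a dimmer probe set of HAS3 by 0.29. UGDH, which makes UDP-glucuronic acid, differed by -0.39 (SE 0.25) and GFPT1, the first enzyme toward UDP-N-acetylglucosamine, by -1.18 (SE 0.29, adjusted p = 0.0636). Without 1 array, UGDH lay between -0.56 and -0.18, and the adjusted p of GFPT1 in limma ranged from 0.0149 to 0.236. Of the 9 measured genes of hyaluronan synthases and precursor enzymes, 7 lay below 0, with a median of -0.31, which was -0.13 without standard array 3. None passed over all genes, 2 had an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. As a list they stood lower in camera (adjusted p = 0.0345), but not with an estimated correlation (adjusted p = 0.871). The estimate for this list was 0.32, against the preset 0.01. In fry, which asks if the genes of a list move one way on balance, the adjusted p was 0.284. The camera call was also lost without standard array 2 (0.202) or 3 (0.174), without high array 1 (0.0764) or 3 (0.103), with array weights (0.293) and with the mean over a gene's probe sets (0.121). It was lost as well with array medians subtracted (0.210) and after quantile normalization (0.0755), where the list's median was -0.44 and -0.40.

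Among the genes of hyaluronan breakdown and binding, 0 of 7 passed in limma, 2 had an unadjusted p under 0.05, and 1 higher and 1 lower passed when adjusted over the list alone. HYAL2, a hyaluronidase, differed by 0.63 (SE 0.17, adjusted p = 0.0819) and the hyaluronan receptor LAYN by -1.05 (SE 0.25, adjusted p = 0.0590). LAYN passed with array medians subtracted (-1.19, 0.0335) and after quantile normalization (-1.16, 0.0305). Without 1 array, the adjusted p in limma ranged from 0.0254 to 0.279 for HYAL2 and from 0.0089 to 0.219 for LAYN. The receptor CD44 differed by 0.25 (SE 0.26), and by 0.09 to 0.46 without 1 array. HYAL3 differed by 0.03 and HYAL1 by -0.03, the latter in the lowest quartile in both groups. Versican (VCAN), a proteoglycan that binds hyaluronan, had means of 11.54 and 11.55, with a 95% interval of the difference from -0.69 to 0.69.

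**Figure D2:**
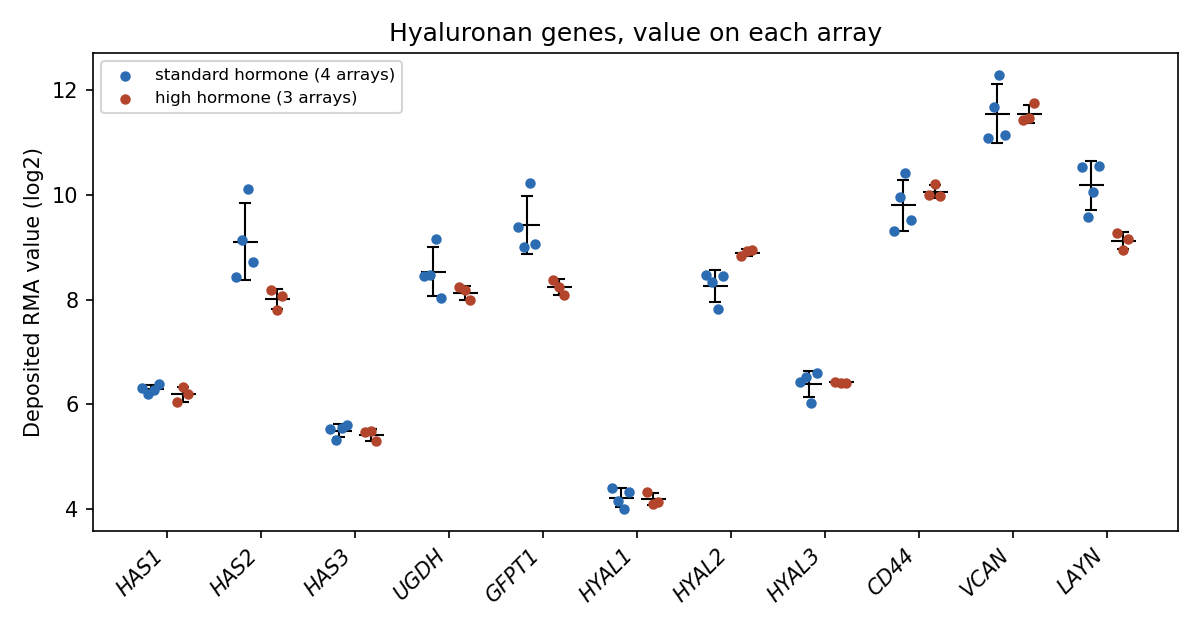
Deposited log2 value (vertical axis) of genes of hyaluronan synthesis, breakdown and binding on each of the 4 standard hormone arrays (blue) and 3 high hormone arrays (red), with group mean and SD in black. HAS2 has means of 9.10 and 8.02, and its standard arrays spread with an SD of 0.74.

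Genes of heparan sulfate synthesis and editing stood higher. Of 25 measured, 22 lay above 0, against 58.4% of all probe sets. In the test over all genes 3 rose (6 when adjusted over the list alone), against 49 of the 927 genes. The median of the 25 was 0.43, and 0.20 without standard array 4, where the list still passed (adjusted p = 0.0223). With array medians subtracted it was 0.30 and after quantile normalization 0.31, and the list passed camera in both (adjusted p = 0.0294 and 0.0121). The 3 were HS3ST2, the 6-O-sulfotransferase HS6ST1 (1.26, SE 0.20, adjusted p = 0.0140) and, named after its values were seen, the N-deacetylase and N-sulfotransferase NDST2 (0.84, adjusted p = 0.00217). The list passed camera (adjusted p = 0.0230), and the call was lost without standard array 1 (adjusted p = 0.174). It was also lost with an estimated correlation (adjusted p = 0.381), though the estimate for this list, -0.0071, lay under the preset 0.01. A higher correlation among its genes thus does not account for that loss. In fry the list's adjusted p was 0.00144. In the chondroitin and dermatan sulfate list, 2 of 20 rose, B3GALT6, a linkage-region enzyme (1.30), and the 6-O-sulfotransferase CHST3 (0.92), and 11 had an unadjusted p under 0.05 (camera adjusted p = 0.434, fry 0.0211). B3GALT6 lost its call with array medians subtracted (1.17, adjusted p = 0.0566). Of 32 proteoglycan core proteins, GPC4 rose and PRG4 fell. Donor synthesis had 0 of 26 passing in limma and 6 at an unadjusted p under 0.05; its member with the smallest p, PGM1, differed by -0.52 (adjusted p = 0.0627) and passed with array medians subtracted (-0.65, 0.0192). Among 19 genes of the nucleotide sugar transporter list, SLC35F2 (1.22) and SLC35E3 (0.93) rose. That list takes members of the SLC35 family by symbol, so not each need carry nucleotide sugars.

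The largest number of calls in a list was in TGF-beta and BMP signalling, where 7 of 35 genes rose and none fell (9 higher when adjusted over the list alone). Over all 927 genes, 49 rose and 5 fell. INHBB (1.95, SE 0.34, adjusted p = 0.0206) and BMP6 (1.91, SE 0.17, adjusted p = 0.00109) rose most. The others, named after their values were seen, were the receptor genes ACVRL1 (1.34) and ACVR1B (0.99) and the ligand genes TGFB3 (1.16), BMP4 (1.14) and BMP7 (0.75), the last from a standard level in the lowest quartile. The list's median was 0.05, it did not pass camera (adjusted p = 0.541), and its adjusted p in fry was 0.0135. ACVR1B's 3 dimmer probe sets did not pass (-0.011 to 0.086, adjusted p from 0.878 to 0.997). Another gene of the list, the procollagen protease BMP1, was also named after its values were seen. It had a called probe set (0.62) beside a brighter one that did not pass (0.29).

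**Figure D3:**
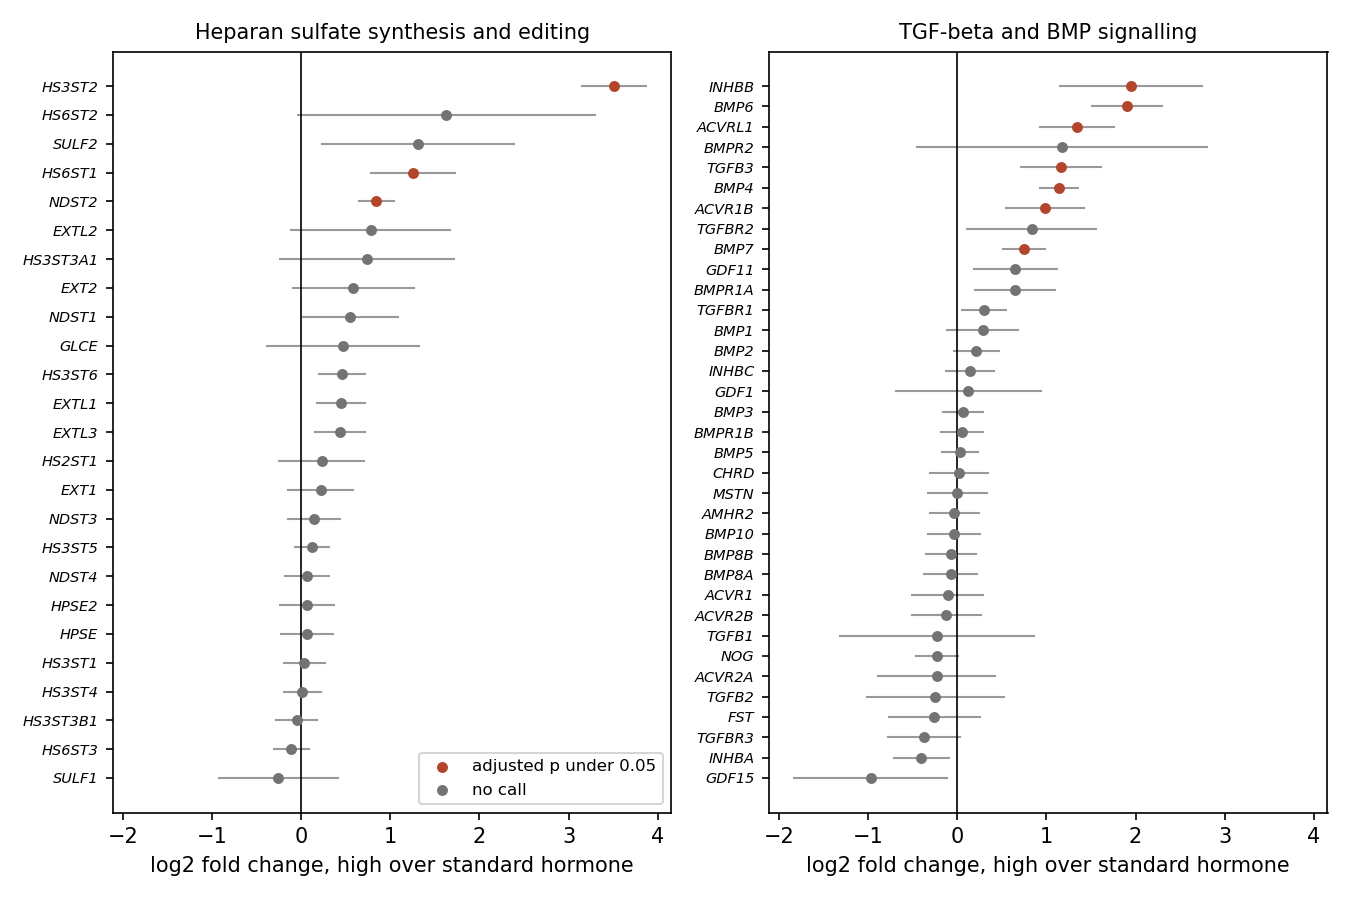
Log2 fold change, high over standard hormone (horizontal axis), of each measured gene of the heparan sulfate list (left) and the TGF-beta and BMP list (right), with its 95% interval. Red points passed an adjusted p of 0.05 and grey ones did not. On the left 22 of 25 genes lie above 0, and on the right 7 of 35 passed, all above 0.

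Of 36 growth factors, 5 rose and 1 fell: FGF13, MDK, the platelet-derived growth factors PDGFD (1.83) and PDGFA (1.32) and MST1 (0.82) rose, and VEGFC fell, the middle 3 named after their values were seen. Adjusted over the list alone, 6 were higher and 2 lower. HGF, hepatocyte growth factor, was also named after its values were seen. It was lower at 2 dimmer probe sets (-0.74, in the lowest quartile in both groups, and -0.54). Its brightest one did not pass (-0.82, SE 0.31, adjusted p = 0.203). Among 17 growth factor receptors and IGF binding proteins, FGFR1 (0.84) and the mannose 6-phosphate and IGF2 receptor IGF2R (0.60) rose (camera adjusted p = 0.434, fry 0.00900). IGF2R, also the 1 call among 32 genes of lysosomal glycan breakdown, lost its call with array medians subtracted (0.46, adjusted p = 0.122). In Wnt signalling, 4 of 29 rose: the receptor FZD8 (1.85), the secreted inhibitor SFRP1 (1.56) and, named after their values were seen, FZD4 (0.97) and FZD3 (0.50). With array medians subtracted, FZD8 (1.71, adjusted p = 0.0523) and FZD3 (0.36, 0.138) lost their calls. Of 20 Notch genes 5 were higher when adjusted over the list alone and 9 had an unadjusted p under 0.05. Neither list passed camera (adjusted p = 0.756 for Wnt and 0.183 for Notch).

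In other glycan lists the calls were few. Of 30 genes of O-GalNAc glycans, GALNT7 (0.81) rose and GALNT5 and GCNT1 fell. ST6GAL1, which adds alpha-2,6-linked sialic acid, was the 1 call among 20 genes of N-glycan trimming and branching (0.90, SE 0.12, adjusted p = 0.00681). With ST8SIA1, the GD3 synthase (0.75, standard level in the lowest quartile), it made 2 of 20 sialyltransferases, and ST8SIA1 was the 1 call among 18 genes of glycosphingolipid synthesis (camera adjusted p = 0.434, fry 0.0135). ST8SIA1 did not pass with array medians subtracted (0.62, adjusted p = 0.0607). None passed in limma among 17 genes of N-glycan assembly (4 at an unadjusted p under 0.05; ALG1 0.76, adjusted p = 0.0507), 11 fucosyltransferases (1; POFUT1 0.21) and 9 genes of ER folding and transport (2; COG8 0.63). Of 13 galectins LGALSL rose (1.04), and of 15 mucins the endothelial sialomucin EMCN (0.83, standard level in the lowest quartile).

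Of 50 C-type lectins and lectin receptors, THBD, the phospholipase A2 receptor PLA2R1 (1.43, and 1.16 at its other probe set) and, named after its values were seen, the scavenger receptor COLEC12 (1.20) rose. PLA2R1's main probe set lost its call with array medians subtracted (1.29, adjusted p = 0.0548). Among 30 inflammatory cytokines and chemokines, a list without CXCL13, 0 passed in limma and 5 had an unadjusted p under 0.05; CX3CL1 differed by 0.59 (adjusted p = 0.0697). Of 25 cytokine receptors, LIFR, the receptor of leukaemia inhibitory factor (1.38, SE 0.14, adjusted p = 0.00217), and IL4R (0.69) rose.

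Markers of other cell types were mostly not called. Of 10 leukocyte markers, 0 passed in limma and 0 had an unadjusted p under 0.05, the smallest p being that of SELPLG (-0.16, adjusted p = 0.710, high level in the lowest quartile). EMCN was the 1 call among 6 endothelial markers. Of 5 fibroblast markers 0 passed and 1 had an unadjusted p under 0.05, PDGFRA (0.84, adjusted p = 0.264). LGALS7, the 1 keratinocyte marker measured, differed by -0.26 (SE 0.36), and NOTCH3, of 3 smooth muscle and pericyte markers, by -0.27 (SE 0.41). Without 1 array NOTCH3 lay between -0.51 and -0.03. Of the textbook glucocorticoid-induced genes 2 were measured, neither called (IL1R2 -0.07, in the lowest quartile in both groups), and of the thyroid hormone-responsive genes and melanocyte markers 0 were measured. The matrix list held 2 measured genes, neither called (NCAM1 0.78, adjusted p = 0.264, and 0.036 at a dimmer probe set).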

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

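The tests of standard array 3 alone and of a mislabelled array were chosen only after the results were seen, and the bounds of the latter were revised once after its value was seen, since its first bounds left it undecided. Over 77 sets of 4 standard hormone values, 3 had a sample far from the others, where chance flags about 1 in 20 (3.85 expected). The median of 51 ribosomal protein probe sets was 12.445 on standard array 3 and 13.127 to 13.226 on the other standard arrays, with 47 of the 51 lowest on array 3. ST6GAL1 read 5.8254 on standard array 4 against 6.1751 to 6.1945 on the others. TGFB3 read 8.1208 on standard array 1 against 7.3999 to 7.4578 on the others.

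The count of 65 probe sets was set against the other ways of splitting the 7 arrays into 3 and 4. Of 35 splits, only the real one (1) gave as many, which argues against chance as the sole source of the count. With so few splits this is the strongest result possible, so chance cannot be excluded. A difference between cultures or batches that follows the groups would rank the same. The highest other split called 47, and it is the one that puts standard array 2 with the high arrays. The hormones themselves stay the biological difference the design names, and which of the pair acts was not tested.

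The standard arrays spread 2.47 times as widely as the high arrays, with a median SD per probe set of 0.228 against 0.0925. On these arrays, standard array 3 alone is argued against, since the ratio was 1.96 without it (95% bootstrap interval over probe sets 1.85 to 2.10). It may account for part, as the ratio was 2.35 to 2.49 without 1 of the other standard arrays. Scaling across arrays as the sole source is argued against too, since the ratio was 2.323 after quantile normalization (2.19 to 2.56). As RMA already includes that step, this is a weak test. The ratio was 2.10 with array medians subtracted and 3.06 with ribosomal protein medians subtracted, so scaling may account for part. These intervals, and the one for array 2 below, resample probe sets as if independent. They do not measure the variation between arrays. On the 109 probe sets called without standard array 2, that array lay 0.4422 of the way (0.371 to 0.561) from the other standard arrays at 0 to the high arrays at 1, the other standard arrays between -0.121 and 0.114 on theirs, and a high array left out the same way between 0.927 and 1.06. That argues against a high array under a wrong label. So does an SD of 0.465 to 0.481 for the difference of array 2 from the high arrays, against 0.159 to 0.221 among those. A mixture of RNA of both groups or a culture that responded in between may still account for part of the spread. Leaving out array 2 changed the ratio little, to 2.39 from 2.47 with all arrays. Gene length stays open for this spread and for the 65 calls: a look at gene span did not exclude it, and is not reported because its gene table names an assembly and the deposited values name none, and GC content was not used.

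More probe sets were higher than lower, 83.1% of the calls. Dim probe sets as the source are argued against: in the brighter 50% the share was 87.23%, with a lower exact 95% bound of 74.3% that treats probe sets as independent. Scaling and a true excess of rises cannot be told apart, since the lowest share over 3 other scalings was 63.64%, between the bounds set for either. A hormone effect on more genes in one direction remains an untested biological possibility.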

How the results depend on the processing

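Chosen after seeing the data were the settings with a separate spread per group, with ribosomal protein medians subtracted and with standard arrays 2 and 3 left out, the pair with the lowest array weights (0.279 and 0.152). Under all settings run, no called gene named in the text changed direction. The count of 65 (54 higher, 11 lower) and the 2 lists passing camera stayed within 1.5 times with the dimmest 25% (64 calls) or 50% (51) left out and with a trended robust prior (61). With array medians subtracted, 24 were lower and 1 list passed, and after quantile normalization 22 were lower and 1 list passed. Of the 65 calls, 53 and 51 were shared with these. Array weights gave 238 calls (166 higher, 72 lower) and 1 list, and separate spreads 108 (90 and 18). An unmoderated statistic gave 20 (17 and 3), and scaling to ribosomal protein medians 22 (18 and 4) with 0 lists. Leaving out standard arrays 2 and 3 gave 306 (188 and 118) and 1 list, and all 65 calls were among them. Leaving out 1 array gave 18 to 109 calls, 16 to 82 higher, 2 to 27 lower and 1 to 2 lists. With the mean over a gene's probe sets 1 list passed, with an estimated correlation 0, and with fry 5. The heparan sulfate list also missed the threshold with ribosomal medians subtracted (adjusted p = 0.0559). The hyaluronan synthesis list missed it there (0.164) and with standard arrays 2 and 3 left out (0.657). With the replicate block, 11 probe sets passed (10 higher, 1 lower) and 1 list, that of hyaluronan synthesis, while the heparan sulfate list had a median of 0.20 and an adjusted p of 0.0548. Whether the numbers pair the samples is not known. Deviations of same-numbered arrays correlated at 0.226, 0.128 and -0.114, and only number 1 correlated best with its own. With so few arrays this cannot settle the pairing, so the block fit cannot be set aside on this ground. The block takes up residual degrees of freedom, and the fit without array 4 of the standard group already gave 40. Except where fewer arrays or probe sets were tested, the cause was not tested.

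HAS2 stayed below 0 in all 18 alternatives, from -1.31 to -0.56, with adjusted p from 0.0342 to 0.421. It passed in 2, array weights (-0.69) and standard arrays 2 and 3 left out (-0.56). Without 1 array it lay between -1.31 and -0.75. The genes that changed sign were not called in the main test. HAS3 read 0.10 with the mean over its probe sets. HYAL1 read 0.0013 with the replicate block and -0.11 to 0.032 without 1 array. HYAL3 read -0.094 to 0.096 without 1 array, -0.10 with array medians subtracted, -0.12 after quantile normalization, -0.076 with array weights, -0.085 with ribosomal medians subtracted and -0.089 with standard arrays 2 and 3 left out. LGALS7 read -0.46 to 0.056 and VCAN -0.16 to 0.25 without 1 array. VCAN read 0.39 with array weights and 0.43 with standard arrays 2 and 3 left out, where its adjusted p was 0.0376. RMA gives no detection call, so signal over background limits the dim genes to an unknown degree.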

Other observations

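Save the last family, the genes and families of this paragraph were picked after their values were seen. All but that family and some of the Siglecs, which are also leukocyte markers, lie outside the fixed lists. Of these, 2 of 3 mucolipins, cation channels of endosomes and lysosomes, rose: MCOLN3 by 1.23 (SE 0.17, adjusted p = 0.00797) and MCOLN2 by 1.11 (adjusted p = 0.0288), while MCOLN1 differed by 0.73 (adjusted p = 0.0636) and by 0.37 at its other probe set. The cytokine gene IL17D rose by 1.55 (SE 0.19, adjusted p = 0.00604) and the inositol phosphate kinase gene ITPK1 by 1.06 (adjusted p = 0.00681), both in every fit that left out 1 array. CD248, a stromal cell-surface glycoprotein, rose by 1.16 (adjusted p = 0.0241). Of 7 measured enzymes of O-mannose glycans, POMGNT1 rose (0.46), a call lost with array medians subtracted (0.33, adjusted p = 0.155). That probe set may cross-hybridise, and the gene's unique one did not pass (0.23, adjusted p = 0.218). In the other families looked at, 0 were called: 7 genes of GPI anchor synthesis, 14 Siglecs, 6 cytosolic sulfotransferases, 6 UDP-glucuronosyltransferases, 6 hedgehog genes and 41 ribosomal protein genes. The carbohydrate sulfotransferases are partly in the fixed lists, and of 15 CHST1 and CHST3, both named by the rule, rose and 13 were not called.

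The standard arrays were not evenly apart. Arrays 1 and 4 differed with an SD of 0.272 over all probe sets (r = 0.995), and every other pair of standard arrays with one of 0.480 to 0.661. Array 2 differed from its nearest standard array, 3, with an SD of 0.480, from arrays 1 and 4 with 0.525 and 0.548, and from the high arrays with 0.465 to 0.481. Picked after the values were seen as the widest gap between arrays 1 and 4 and arrays 2 and 3, BMPR2, a BMP receptor gene, read 7.46 and 7.29 on the former and 9.88 and 9.75 on the latter. NEU1, a lysosomal sialidase gene, had the widest gap in the other direction, with 9.82 and 9.29 against 7.82 and 7.81.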
